A study of Mus musculus with 2 samples.

How the data were processed

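Single-cell RNA sequencing of As4.1 cells was analysed from the deposited files of 2 libraries, 1 of cells treated with 10 µM H89 and 1 of cells given DMSO. For each condition 600000 cells were plated in duplicate flasks, and 4000 cells were targeted for capture with 10x Genomics 3' chemistry. Whether the duplicate flasks were pooled was not given in the sources used here. Chromatin data of the same study and its other inhibitors were not part of the files.

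The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 7.0.1 per the file headers and filtered to called cells. The build was mm10 per the submitters' processing notes, which list another Cell Ranger version. The gene annotation and whether intronic reads were counted were not given in the sources used here. Each sample had 2 identical copies of its matrix, of which 1 was used. The matrices list 32285 genes, and 23244 had a UMI in the cells kept. Positions and gene types came from a GENCODE annotation of the same build, in which 32235 of the 32285 gene identifiers were found.

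Of 4095 H89 barcodes and 3410 DMSO barcodes, those with fewer than 1000 detected genes (39 and 15) or with over 20% mitochondrial UMIs (22 and 21) were removed. Some barcodes met both criteria, so 58 and 31 were removed in all. The 4037 and 3379 cells kept had 139601506 and 112938822 UMIs. At these depths 3 UMIs, the limit that a count of 0 allows, correspond to 0.0215 CPM with H89 and 0.0266 CPM with DMSO.

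UMIs were summed over the cells of each library and divided by all summed UMIs to give counts per 1000000 UMIs (CPM). Cells are not replicates, and each treatment had 1 library, so no test was run and no p-value or standard error was computed. CPM values carry exact Poisson intervals, ratios of H89 over DMSO carry exact conditional binomial intervals, and shares of cells carry Clopper-Pearson intervals, all at 95% and all for counting error only. Counts of genes by size used genes with a mean CPM over the 2 libraries of at least 10.

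The named genes, the gene lists, the filters and the alternatives below were chosen before the data were examined, except where the closing section says otherwise. Named were Ren1, Brd4, Ep300, Crebbp, Prkaca and Prkacb, the 12 highest and 12 lowest ratios among genes with a mean CPM of at least 10, and the 8 highest and 8 lowest among genes with a mean CPM of at least 100. Predicted gene models, mitochondrial genes and ribosomal protein genes were left out of these ranks. In each fixed list, up to 4 members with the largest absolute log2 ratio were named among members with a mean CPM of at least 5, and the text prints some or all of them. Levels of Ptprc, Tyrobp, Pecam1, Rgs5, Mcam, Csf1r, Lyz2 and Itgam are also printed, as members of the marker lists that did not reach that minimum.

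The 30 fixed lists were renin cell genes, regulators of renin transcription, PKA and cAMP pathway components, cAMP and CREB target genes, smooth muscle contractile genes, YAP and SRF target genes, and extracellular matrix genes. They also held S phase genes, G2 and M phase genes, p53 target genes, integrated stress and amino acid response genes, ER folding genes, cytosolic heat shock genes, cholesterol synthesis and uptake genes, and fatty acid synthesis and storage genes. Further lists were hypoxia and glycolysis genes, mitochondrially encoded genes, nuclear encoded respiratory chain genes, cytosolic ribosomal protein genes, lysosome and autophagy genes, secretory granule and prohormone processing genes, interferon response genes, and NF-kB, cytokine and acute phase genes. The last were NRF2 and oxidative stress genes, Notch and TGF-beta target genes, chromatin and histone acetylation factors, and markers of pericytes and mesangial cells, endothelium, kidney epithelium and leukocytes. For each list the median log2 ratio of its members with a mean CPM of at least 5 was placed among the medians of 10000 random lists of the same size, drawn from genes in the same 10 bins of mean expression.

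For shares of cells and quantiles, each cell was thinned to 10000 UMIs by sampling without replacement with a fixed seed. The 85 H89 cells and 44 DMSO cells with fewer UMIs were left out. Thinned counts of both libraries together were scaled to 10000 and log transformed with scanpy 1.11.5. Phase classes came from its cell cycle scores with the S phase list and the G2 and M phase list. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 0.5. Scrublet was run on each library and marked 1 cell in each as a doublet, so it did not separate doublets here and they remain in the values. Clusters 2 and 7 were compared with the other clusters within each library, from UMIs summed over their cells. Correlations with Ren1 across cells used thinned, log-transformed counts of 6569 genes.

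The alternatives were scaling by TMM in edgeR 4.0.16 or by size factors in DESeq2 1.42.0 (R 4.3.3), a total without mitochondrial and ribosomal protein genes, and equal weight for each cell. Others were all barcodes, a stricter cell filter of 2500 genes and 10% mitochondrial UMIs, removal of marked doublets, thinning to 5000 UMIs or none, other minimum CPM values, at least 3 Ren1 UMIs, single phase classes, and Leiden resolutions of 0.25 and 1.0. The edgeR and DESeq2 factors served for scaling alone. TMM factors were 0.995 for H89 and 1.00 for DMSO, and DESeq2 size factors were 1.11 and 0.900. The steps for ratios and intervals were tested on simulated data of 8625 genes, in which 200 were given 3-fold or 5-fold differences. All 200 passed 2-fold and 0% of the 8425 others did, and 95.1% of the intervals held the true ratio. The simulated counts were Poisson draws, the error that the intervals assume, so these results were largely fixed in advance. They check the computation and say nothing about the spread between cells or cultures.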

Results

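Gene expression was measured in single cells of As4.1, a mouse line derived from a kidney tumour that makes large amounts of renin mRNA. Cells were given 10 µM H89, an inhibitor of protein kinase A (PKA) that is known to act on other kinases too, or the same volume of its solvent DMSO. Per the labels, doses were given at 0, 24 and 48 h and the cells were harvested after 48 h, and whether the last dose came just before harvest was not stated. Each treatment had 1 droplet library, so there were no replicates, no test was possible and no p-value is given. Intervals are exact 95% intervals that cover counting error only. The H89 library held 4037 cells after filtering, with 139601506 UMIs (counted transcripts) and a median of 31105 UMIs and 6380 genes per cell. The DMSO library held 3379 cells with 112938822 UMIs and a median of 31223 UMIs and 6219 genes per cell.

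The comparison of H89 with DMSO asked how renin mRNA and other transcripts differ in renin-producing cells given an inhibitor of PKA. Whether PKA activity fell was not measured in these libraries. Ren1, the renin gene, was 4.20-fold lower in the H89 library. Genes of amino acid synthesis and of the integrated stress response, among them Asns and Psat1, were lower by a median of 2.93-fold over 33 measured genes. Interferon response genes, among them B2m and Irf7, were higher by a median of 2.35-fold over 31 measured genes. Lysosome genes and cholesterol synthesis genes were higher as groups, and hypoxia and glycolysis genes and nuclear encoded respiratory chain genes were lower as groups. Most other genes were close. Of 8779 genes with a mean of at least 10 counts per 1000000 UMIs (CPM) over the 2 libraries, 89.5% lay within 1.5-fold, 212 (2.41%) were at least 2-fold higher in the H89 library and 96 (1.09%) at least 2-fold lower. The median log2 ratio of H89 over DMSO was 0.03.

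Ren1 (ENSMUSG00000070645) lies on chromosome 1 of mm10 from 133350510 to 133360325 on the + strand. It was the gene with rank 5 by UMIs in the DMSO library and rank 92 in the H89 library. The DMSO library had 648986 Ren1 UMIs, or 5746 CPM (5732 to 5760), and the H89 library 190948, or 1368 CPM (1362 to 1374). The level was 4.20-fold lower in the H89 library (4.18 to 4.22), a log2 ratio of -2.07. Among the 8779 genes with a mean CPM of at least 10, Ren1 had the ratio of rank 17 from the lowest.

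The lower Ren1 level was seen across the H89 cells rather than in a few of them. After every cell was thinned to 10000 UMIs, the median cell had 5 Ren1 UMIs in the H89 library and 47 in the DMSO library. The quartiles were 1 and 17 in the H89 library and 25 and 81 in the DMSO library. A Ren1 UMI was found in 3235 of 3952 H89 cells, 81.9% (80.6 to 83.0, Clopper-Pearson), and in 3307 of 3335 DMSO cells, 99.2% (98.8 to 99.4). Without thinning, at median depths of 31105 and 31223 UMIs, the shares were 92.3% and 99.9%. Thinning left out 85 shallower H89 cells and 44 shallower DMSO cells. No cell type that lacks Ren1 was present, so the part of these shares that comes from free RNA in the droplets is open. In the H89 library 47.5% of cells (46.0 to 49.1) lay under the 5th percentile of DMSO cells, which was 5 Ren1 UMIs. Another 6.88% (6.11 to 7.72) lay above the DMSO median. The 10% of cells with the most Ren1 UMIs held 48.3% of the Ren1 UMIs in the H89 library and 28.1% in the DMSO library.

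**Figure D1:**
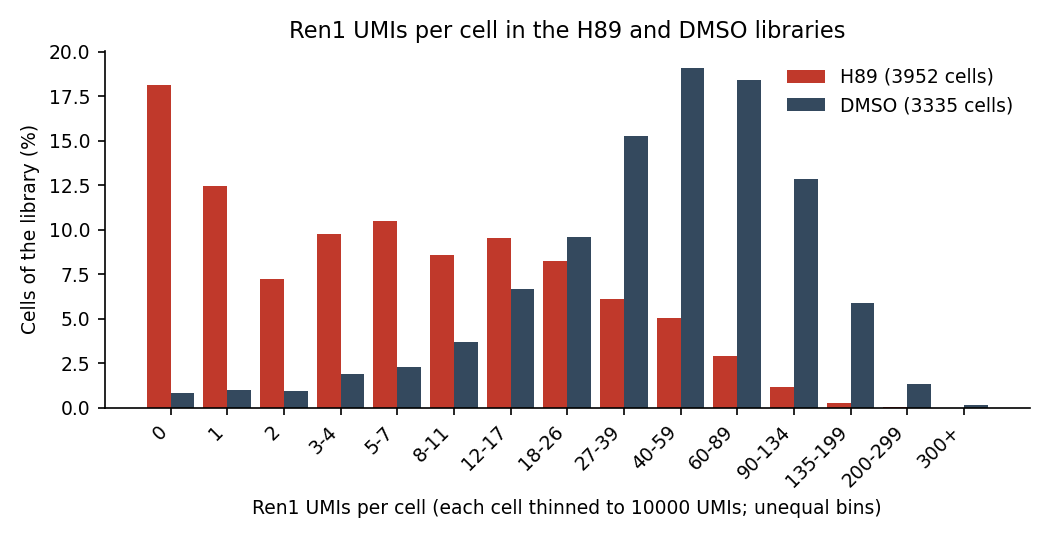
Ren1 UMIs per cell after each cell was thinned to 10000 UMIs (x axis, unequal bins) against the share of the library's cells in percent (y axis), for 3952 H89 cells (red) and 3335 DMSO cells (dark blue). Most H89 cells lie to the left of most DMSO cells, with medians of 5 and 47 Ren1 UMIs, and 18.1% of H89 cells against 0.840% of DMSO cells have none.

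Ren1 was lower in the H89 library in each cell cycle phase class, which is a range of a score and not a cell type. In cells classed as G1 the level was 722 CPM with H89 and 5985 CPM with DMSO, 8.29-fold lower. In the S class the values were 925 and 5413 CPM, 5.85-fold lower, and in the G2M class 1873 and 5937 CPM, 3.17-fold lower. The S and G2M classes together held 77.2% of H89 cells (75.9 to 78.5) and 90.8% of DMSO cells (89.8 to 91.8). The G1 class held 22.8% of H89 cells (21.5 to 24.1) and 9.18% of DMSO cells (8.22 to 10.2). Within 0.05 score units of the G1 boundary lay 324 H89 cells (8.20%) and 234 DMSO cells (7.02%), and the part of the score difference that comes from free RNA is open. In the summed libraries, the S phase list had a median log2 ratio of -0.14, with 36 of 43 members lower, for example Rad51ap1 (-0.49) and Exo1 (-0.49). That median lay at percentile 0.16 of 10000 random lists matched on mean expression, the comparison used for every list. Random members were drawn independently, whereas members of a list can vary together, and each treatment had 1 library. The percentiles therefore describe these 2 libraries and do not test a list. The S phase list had medians of -0.35 in the G1 class, 0.12 in the G2M class and 0.02 in clusters 2 and 7. Mitosis genes of the G2 and M phase list had a median of -0.12 (percentile 0.88), with 42 of 54 members lower. Among these was Ndc80 (-0.55), a kinetochore gene, whereas Psrc1 was higher (0.88). The G2 and M phase list had medians of -0.29 in the G1 class, -0.02 in the S class and 0.02 in the G2M class.

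The genes of the PKA catalytic subunits, and of Brd4, p300 and CBP, which the study's design names as targets of inhibitors not used in these libraries, were within 1.5-fold. Prkaca and Prkacb, which encode catalytic subunits of PKA, had log2 ratios of 0.17 and 0.06. Brd4, a reader of acetylated histones, had -0.10, and the histone acetyltransferase genes Ep300 and Crebbp had -0.05 and -0.01. Among regulators of renin transcription 18 of 33 measured members were higher and 15 lower, none by 2-fold, with a median log2 ratio of 0.04 (percentile 64.1). Foxd1, a transcription factor of the renin cell lineage, had 0.64, Nr4a1 0.59, Ebf1 0.51 and the vitamin D receptor gene Vdr -0.51. PKA and cAMP pathway components had a median of 0.08 (percentile 85.6), with 18 of 32 higher. The regulatory subunit gene Prkar2b was 2.27-fold higher, the PKA inhibitor gene Pkig was 1.82-fold higher and the phosphodiesterase gene Pde10a had a log2 ratio of -0.50. cAMP and CREB target genes had a median of 0.25 (percentile 99.8), with 15 of 24 higher and 9 lower, and medians of 0.08 in the G1 class, 0.10 in the S class, 0.42 in clusters 2 and 7 and 0.40 for members of at least 20 CPM. The immediate early genes Fosb (2.64-fold) and Fos (2.08-fold) and the Id3 gene (2.44-fold) were higher, and the kinase gene Sik1 was 2.03-fold lower. Chromatin and histone acetylation factors had a median of -0.03 (percentile 20.8), with 17 of 41 higher. The deacetylase gene Hdac5 was 2.83-fold higher. The renin cell genes went both ways. Of 20 members only 12 reached the minimum of 5 CPM. Among those that did not were Rgs5, with 5 H89 and 11 DMSO UMIs, and Mcam, with 9 and 30. Of the 12 measured members, 8 were higher and 4, Ren1 among them, lower. The median was 0.29 (percentile 98.97), and 0.02 for members of at least 20 CPM. Sparcl1 was 3.63-fold, Aldh1a1 3.46-fold and Cd59a 1.90-fold higher, at low mean levels of 6.80, 6.10 and 8.82 CPM.

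Genes of amino acid supply made up much of the lower end of the ratios. Of the 12 named genes with the lowest ratios, 8 belong to the fixed list of integrated stress and amino acid response genes, many of which are driven by the transcription factor ATF4. Chac1, a glutathione-degrading enzyme gene, was 12.97-fold lower (11.9 to 14.2), at 3.78 CPM with H89 and 49.1 with DMSO. Trib3 was 10.2-fold lower, and Asns, the asparagine synthetase gene, was 8.64-fold lower (8.29 to 9.02), at 17.8 and 154 CPM. The serine synthesis genes Psat1, Psph and Phgdh were 5.395-fold, 5.03-fold and 3.49-fold lower. The amino acid transporter genes Slc7a1 and Slc7a5 were 5.10-fold and 4.74-fold lower, Sesn2 was 4.85-fold lower, and the abundant genes Nupr1 and Mthfd2 were 4.56-fold and 4.47-fold lower. In the whole list 31 of 33 measured members were lower, 26 of them by at least 2-fold, and the median log2 ratio was -1.55 (percentile 0, quartiles -2.24 and -1.004). The hormone gene Fgf21 had the lowest ratio of the list, at 0.272 CPM against 19.2 CPM, 70.6-fold lower (51.3 to 100). The other genes among the 12 lowest were Tnnc1 (8.13-fold), a troponin gene, Gpt2 (7.63-fold), an alanine transaminase gene, Cdh12 (6.56-fold) and Ccnb1ip1 (4.65-fold). The abundant lipid flippase gene Atp8a1 was 4.19-fold lower.

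Other stress lists had medians closer to 0. ER folding genes had a median log2 ratio of 0.05 (percentile 80.8), with 15 of 24 higher, although Herpud1 was 2.80-fold lower. NRF2 and oxidative stress genes had a median of 0.08 (percentile 88.0), with 18 of 33 higher. The metallothionein gene Mt1 was 4.51-fold and the epoxide hydrolase gene Ephx1 3.67-fold higher, and the cystine transporter gene Slc7a11 was 2.23-fold lower. The other member at least 2-fold lower was Trib3, by 10.2-fold, and both also belong to the integrated stress list. Cytosolic heat shock genes had a median of -0.18 (percentile 0.785), with 12 of 19 lower. Despite its name the list also held the mitochondrial chaperonin gene Hspd1, which had -0.73. The small heat shock gene Cryab was 4.37-fold higher. Of the p53 target genes, 17 of 20 were higher, with a median of 0.29 (percentile 99.7), among them Trp53inp1 (2.31-fold). Gadd45a was 2.61-fold and Plk2 2.09-fold lower, and the third member at least 2-fold lower was Sesn2. The p53 list median was 0.50 in the G1 class, 0.15 in the G2M class and 0.16 in clusters 2 and 7.

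Interferon response genes stood at the upper end. Of 31 measured members 29 were higher in the H89 library, 20 of them by at least 2-fold, with a median log2 ratio of 1.23 (percentile 100, quartiles 0.61 and 1.89). B2m, the light chain of MHC class I, was at 531 CPM with H89 and 70.5 CPM with DMSO, 7.53-fold higher (7.36 to 7.71). Irf7, a transcription factor of the interferon response, was 6.94-fold higher, the antiviral gene Oas1a 4.83-fold and Irf9 4.79-fold. Among thinned cells, a B2m UMI was found in 97.0% with H89 and 46.4% with DMSO, and the part of these shares that comes from free RNA is open. Outside the list, Ifi27l2a, an interferon-inducible gene, had the highest ratio of all named genes. It was at 1501 CPM against 76.0 CPM, 19.8-fold higher (19.3 to 20.2). The chemokine gene Ccl8 was 16.9-fold higher, Phf11d 9.73-fold and the interferon-inducible GTPase gene Iigp1 7.42-fold. NF-kB, cytokine and acute phase genes had a median of 0.33 (percentile 99.7), with 13 of 14 higher, among them the chemokine gene Ccl7 (2.87-fold) and the adhesion gene Vcam1 (2.43-fold). Of 21 leukocyte markers only Cd68, which encodes a lysosomal membrane protein, passed the minimum of 5 CPM, at 11.9 CPM with H89 and 2.57 CPM with DMSO, 4.63-fold higher (list percentile 99.6). The pan-leukocyte gene Ptprc had 4 UMIs in the H89 library and 1 in the DMSO library, and Tyrobp had 1 in each.

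Genes of the lysosome and of cholesterol synthesis were higher as groups. Of 45 lysosome and autophagy genes 41 were higher, 7 of them by at least 2-fold, with a median log2 ratio of 0.61 (percentile 100). Gpnmb, a glycoprotein gene linked to lysosomal stress, was 13.3-fold higher (12.6 to 14.1), at 149 CPM against 11.2 CPM. The lysosomal enzyme genes Hexa and Tpp1 were 2.79-fold and 2.41-fold higher, and Fnip2 was 2.22-fold higher. The leukocyte and lysosome gene Cd68 moved with this group by 4.63-fold. All 24 measured cholesterol synthesis and uptake genes were higher, with a median of 0.46 (percentile 100), which was 0.11 in the G1 class. Nsdhl (2.32-fold), Dhcr24 (2.31-fold), Hsd17b7 (2.17-fold) and Sqle (1.76-fold) encode enzymes of the sterol pathway. Fatty acid synthesis and storage genes had a median of 0.16 (percentile 96.9), with 13 of 21 higher, among them Fads1 (2.00-fold) and Gpam (1.85-fold), but medians of 0.00196 in the G1 class and 0.04 in clusters 2 and 7. Secretory granule and prohormone processing genes had a median of 0.24 (percentile 98.4), with 9 of 13 higher and a median of 0.40 in clusters 2 and 7. Cpe, which encodes carboxypeptidase E, was 2.02-fold higher, and the granin gene Scg2 was 1.68-fold lower.

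Hypoxia and glycolysis genes and nuclear encoded respiratory chain genes were lower as groups. Of 27 hypoxia and glycolysis genes 26 were lower, 5 of them by at least 2-fold, with a median log2 ratio of -0.54 (percentile 0). The carbonic anhydrase gene Car9 was 2.84-fold, Ero1l 2.69-fold, Egln3 2.35-fold and the phosphofructokinase gene Pfkp 2.12-fold lower. Of 69 nuclear encoded respiratory chain genes 66 were lower, none by 2-fold, with a median of -0.34 (percentile 0). The ATP synthase gene Atp5b was 1.69-fold and the cytochrome c gene Cycs 1.62-fold lower. Of the mitochondrially encoded genes of the same complexes 11 of 13 were higher, with a median of 0.09 (percentile 92.3). That median lay within the middle 95% of the random lists, -0.20 to 0.15. It was 0.18 in the G1 class and 0.01 in clusters 2 and 7. The cytochrome oxidase genes mt-Co1 and mt-Co3 were 1.53-fold and 1.42-fold higher, and mt-Nd6 was 1.71-fold lower. Mitochondrial UMIs made up 4.12% of the H89 library and 3.401% of the DMSO library. Cytosolic ribosomal protein genes had a median of -0.10 (percentile 14.7), with 58 of 81 lower and medians of -0.03 in the G1 class and -0.18 in clusters 2 and 7, and Rpl22l1 was 1.74-fold higher.

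Matrix genes and several secreted factors were higher. Of 31 extracellular matrix genes 23 were higher, 5 by at least 2-fold and none lower by 2-fold, with a median log2 ratio of 0.28 (percentile 100), which was 0.06 in the G1 class. Lox, which encodes a collagen cross-linking enzyme, was 5.50-fold, the laminin gene Lama4 2.27-fold, the matrix protease gene Mmp14 2.10-fold and the collagen gene Col3a1 2.06-fold higher. Among abundant genes outside that list, the growth factor gene Vegfd was 4.95-fold higher, the BMP antagonist gene Grem1 3.98-fold, Thbs2 3.85-fold and Lgals3bp 5.52-fold. Pi15 (8.61-fold), Svep1 (8.21-fold), Ang2 (7.52-fold), Gask1b (6.89-fold) and Cilp (6.64-fold) were the remaining genes among the 12 highest. Smooth muscle contractile genes had a median of 0.22 (percentile 97.8), with 9 of 12 higher, among them Mylk (1.90-fold) and Smtn (1.61-fold), and medians of 0.11 in the G1 class and 0.40 in clusters 2 and 7. YAP and SRF target genes had a median of 0.06 (percentile 73.4), with 11 of 20 higher. Axl was 1.92-fold higher, whereas Rbms3 and F3 had log2 ratios of -0.85 each. Notch and TGF-beta target genes had a median of 0.59 (percentile 99.99), with 8 of 9 higher and a median of 0.92 in clusters 2 and 7. Id2 and Id3, inhibitors of differentiation, were 2.98-fold and 2.44-fold higher.

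**Figure D2:**
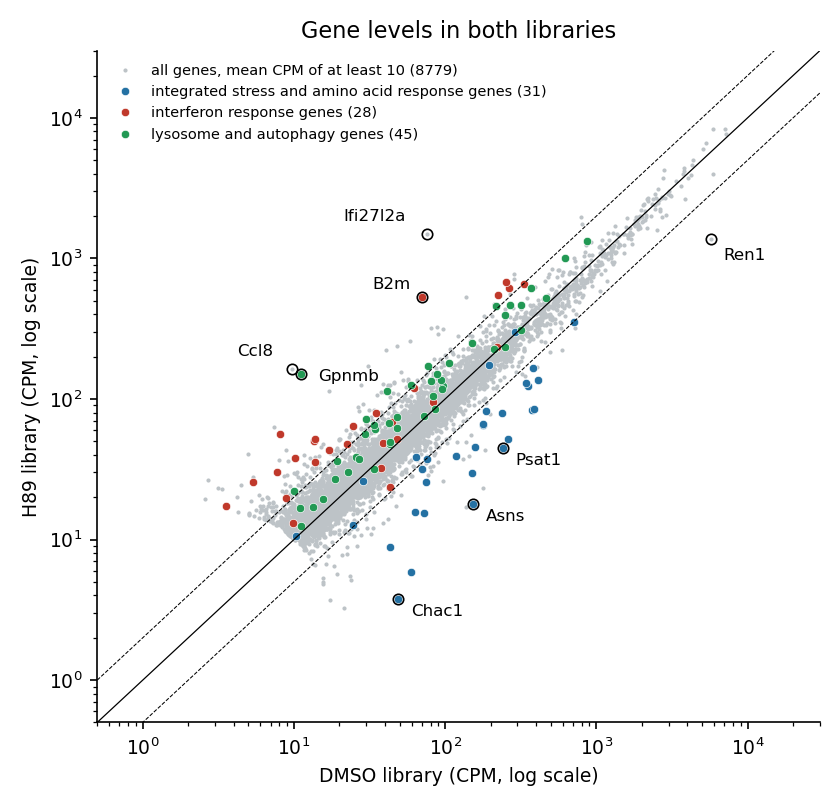
CPM in the DMSO library (x axis, log scale) against CPM in the H89 library (y axis, log scale) for 8779 genes with a mean CPM of at least 10, each point a gene, with equal levels on the solid line and 2-fold differences on the dashed lines. Integrated stress genes (blue) lie mostly below the lines, interferon genes (red) mostly above, and Ren1 lies at 5746 CPM with DMSO and 1368 CPM with H89.

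Few markers of kidney epithelium, endothelium or leukocytes reached the minimum level. Fibroblast markers, a further fixed set with Pdgfra and Col3a1 among them, were more common in the clusters described below. In clusters 1, 2, 3, 4, 5 and 7, 4 of them were over 20 CPM, with 3 in cluster 8 and 2 in cluster 6. Only 1 renin cell marker was over 20 CPM in each cluster. Of 20 kidney epithelial markers none reached a mean of 5 CPM. Pericyte and mesangial markers had a median log2 ratio of 0.45 (percentile 99.3), with 5 of 7 measured members higher, among them the endothelin receptor gene Ednra (2.01-fold) and Pdgfra (1.61-fold), and medians of 0.25 in the G1 class and 0.69 for members of at least 20 CPM. Of the endothelial markers 3 were measured, with a median of 0.27 (percentile 79.2), which was 0.03 in the G1 class. Kdr was abundant in both libraries, at 603 CPM with H89 and 502 CPM with DMSO, whereas Pecam1 had 101 and 85 UMIs.

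**Figure D3:**
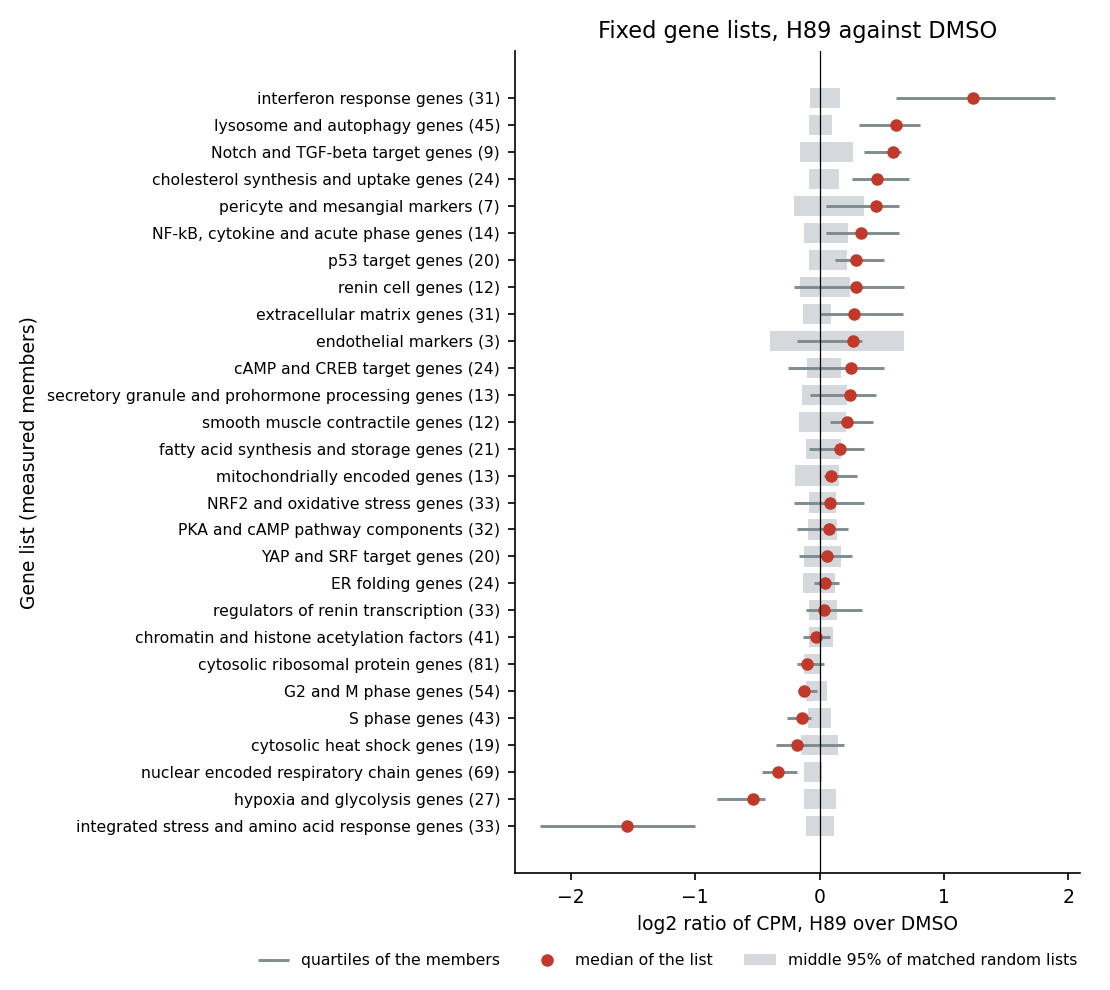
Median log2 ratio of CPM, H89 over DMSO (x axis), for each fixed list with at least 3 measured members (y axis, number of members in brackets). Red points are medians, lines span the quartiles of the members, and grey bars hold the middle 95% of the medians of random lists matched on mean expression. The interferon list (1.23) and the integrated stress list (-1.55) lie farthest from 0.

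Joint clustering of both libraries gave 8 clusters of cells, given here by number only. Clusters 1, 3 and 6 were mostly of the H89 library and clusters 4 and 5 mostly of the DMSO library, so they can reflect the libraries themselves. At this resolution of 0.5, clusters 2, 7 and 8 held cells of both. Clusters 2 and 7, with 605 H89 cells and 672 DMSO cells, were joined because Khdrbs3, Slc14a1, Acaa1b and Wnt3 led both. Ren1 was 4.35-fold lower with H89 within them, at 960 and 4181 CPM, and 4.30-fold lower within the other clusters, at 1438 and 6183 CPM. Within each library, genes of chromosomes 15 and 13 were lower in clusters 2 and 7 than in the other clusters. The median log2 ratio on chromosome 15 was -0.44 with H89 over 361 genes and -0.45 with DMSO over 354 genes. On chromosome 13 it was -0.27 over 327 genes and -0.30 over 319 genes.

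**Figure D4:**
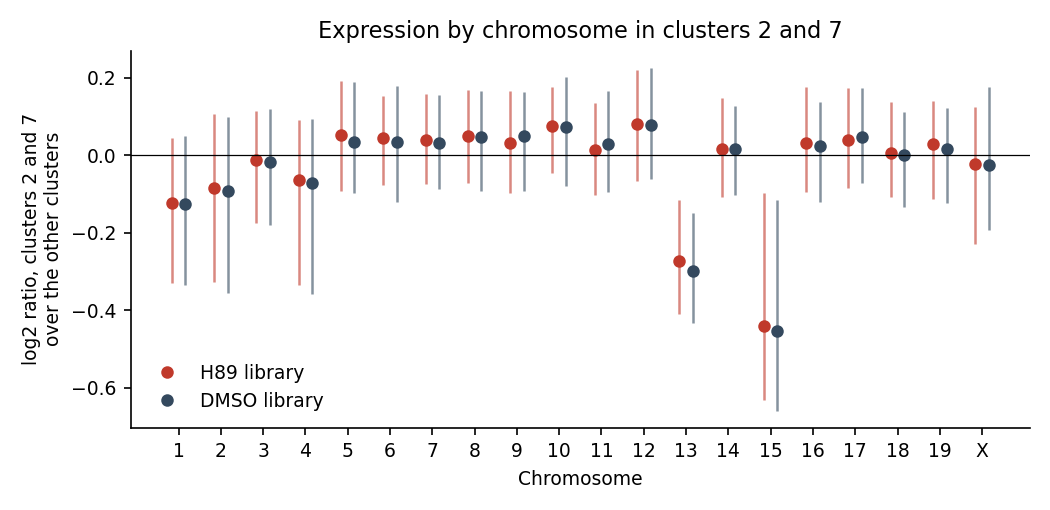
Median log2 ratio of CPM in clusters 2 and 7 over the other clusters (y axis) for the genes of each chromosome (x axis), relative to the median of all genes, in the H89 library (red) and the DMSO library (dark blue), with lines spanning the quartiles of the genes. Chromosome 15 (-0.44 and -0.45) and chromosome 13 (-0.27 and -0.30) lie lowest in both libraries.

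With 1 library per treatment, a difference between the cultures or libraries cannot be separated from one between the treatments. The medians of 7 lists near 0, between -0.14 and 0.08, changed sign under at least 1 alternative, and the renin cell list had a median of 0.02 when members needed a mean of at least 20 CPM.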

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

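No paired analysis was possible because each treatment had 1 library, and for the same reason no call of a test could be lost. The phase and cluster splits of the gene lists, the S and G2M classes for Ren1, and the removal of cells with over 60000 UMIs were chosen after seeing the data. The same holds for the joining of clusters 2 and 7 and for the Ren1 values within them and within the other clusters. Ren1 was lower in the H89 library under every alternative run. Its log2 ratio was -2.07 in the main analysis, -2.06 with TMM, -2.13 with each cell counted alike, -2.13 with thinned cells, -2.12 without cells over 60000 UMIs, -2.12 in clusters 2 and 7 and -2.10 in the other clusters. It was -3.05 in the G1 class, -2.55 in the S class and -1.66 in the G2M class, and the cause was not tested. The counts of genes at least 2-fold apart depended on the filter for low counts. With a mean of at least 50 CPM 70 were higher and 53 lower. Without a filter, and with 0.5 counts added to each gene in each library, 2495 were higher and 3102 lower. Genes with few UMIs then enter, and the added counts were not varied on their own. The share of cells with a Ren1 UMI was 72.9% with H89 and 98.2% with DMSO at 5000 UMIs, 92.3% and 99.9% without thinning, and 62.2% and 97.2% for at least 3 Ren1 UMIs, as depth and the stricter criterion set these shares. The S and G2M classes held 75.6% and 88.2% of cells at 5000 UMIs, and the cause was not tested. Leiden resolutions of 0.25 and 1.0 gave 5 and 14 clusters, numbered anew, and the mixing of the libraries depended on the resolution. At 0.25 cluster 5 held 404 H89 cells and 672 DMSO cells. At 1.0 cluster 5 held 215 and 255 and cluster 7 held 84 and 36. The other clusters at these resolutions were mostly of 1 library. Whether the cells of clusters 2 and 7 stayed together was not tested. Of 405 alternative values of the 29 list medians, 396 kept the sign. The other 9 lay in 7 lists, and their cause was not tested. Some alternatives, such as removal of 1 marked doublet per library or another scaling, could hardly change a sign. The count of kept signs is therefore no measure of how firm the medians are. In the G1 class PKA and cAMP components had -0.00459, YAP and SRF targets -0.0267, ER folding genes -0.0756 and chromatin factors 0.0106. In clusters 2 and 7 S phase genes had 0.0165 and chromatin factors 0.0212. In the G2M class S phase genes had 0.12 and G2 and M phase genes 0.0214, in cells that had been chosen by these genes. NRF2 genes had -0.0397 for members of at least 20 CPM, where the median was 0.41 for secretory granule genes, 0.18 for YAP and SRF targets, 0.09 for regulators of renin transcription, 0.02 for renin cell genes and 0.0108 for PKA and cAMP components. In the G1 class the median was 0.11 for cholesterol genes, 0.06 for matrix genes, 0.50 for p53 targets, -0.35 for S phase genes, -0.29 for G2 and M phase genes and -0.03 for ribosomal protein genes. The median of nuclear encoded respiratory chain genes was -0.35 without cells over 60000 UMIs, -0.39 in clusters 2 and 7, and -0.42, -0.36 and -0.27 in the G1, S and G2M classes, and the cause was not tested. Another scaling moved the median of all genes by at most 0.0137 on the log2 scale. Depth limits the shares of cells with a UMI, and the ratios of genes near the level that 3 UMIs give, 0.0215 CPM with H89 and 0.0266 CPM with DMSO.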

Other observations

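The tests of scaling, of culture medium and density, of leukocyte transcripts, of Ifi27l2a, of the summed interferon genes per cell and of chromosome copy number, the limits set to free RNA, and the phase and cluster splits of the gene lists were chosen after the results were seen. At resolution 0.5, clusters 2 and 7 formed a subpopulation seen in both libraries. In the DMSO library Slc14a1, a urea transporter gene, was at 251 CPM in these clusters and 12.6 CPM in the others, and in the H89 library at 189 and 14.0 CPM. S100g, a calcium-binding protein gene, was at 1877 and 159 CPM with DMSO and at 1640 and 159 CPM with H89. Grem1 was at 5.16 CPM in these clusters and 101 CPM in the others with DMSO, and at 36.0 and 368 CPM with H89. In both libraries 62 of 8468 genes were at least 2-fold higher in clusters 2 and 7 and 93 at least 2-fold lower. These genes helped to define the clusters, so the counts describe the clusters and do not test them. Across 8503 genes, which are not independent replicates, the H89 over DMSO ratios in clusters 2 and 7 and in the other clusters had r = 0.904.

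Among DMSO cells, Ren1 went with other genes from cell to cell. Over 6569 genes the most positive correlations with Ren1 included Gapdh (r = 0.31), a glycolysis gene, and Igfbp4 (r = 0.24). The most negative included the matrix genes Ogn (r = -0.21) and Lox (r = -0.19) and the guidance gene Sema3a (r = -0.20). The 100 genes with the most negative correlation had a median log2 ratio of H89 over DMSO of 0.61, and the 100 with the most positive a median of -0.30. Across genes, which are not independent replicates, the correlation with Ren1 in DMSO cells and the log2 ratio had r = -0.34 (Spearman -0.27). For the correlation with Ren1 in H89 cells, r was -0.46. The mitosis genes Cdca3 and Ccnb2 had 0.33 and 0.31 with Ren1 in H89 cells but 0.07 and 0.05 in DMSO cells. The DMSO cells included clusters 2 and 7, where Ren1 was at 4181 CPM against 6183 CPM in the others, so subpopulations can add to these correlations.

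Ren1 was 4.20-fold lower in the H89 library. Of the genes with a mean CPM of at least 10, 0.182% had a lower ratio than Ren1, an order that no factor per library changes, which argued against scaling as the cause. A shift of phases as the whole cause was argued against by a smallest size of 1.66 over the 3 phase classes, and a minority of cells by a smallest size of 2.25 over the 3 quartiles of Ren1 UMIs per cell, with a lower DMSO quartile of 25 UMIs against an upper H89 quartile of 17 and at most 4.78 from free RNA in DMSO cells, as 0.840% of them had none. An effect of H89 on renin mRNA, which the design names, remains open and untested against a difference between the cultures, since each treatment had 1 library.

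Integrated stress and amino acid response genes were lower in the H89 library. The list median had a size of at least 1.22 in each of the 3 phase classes and of at least 1.39 in both sets of clusters, which argued against different phase shares or subpopulation shares as the whole cause. Depleted medium or higher density in the DMSO culture could also give this pattern and cannot be told apart from an effect of H89, since both cultures were sampled once. The hypoxia and glycolysis list went in the direction this needs, with a median of -0.54, but the YAP and SRF list, with a median of 0.06, decided nothing. An effect of H89, through PKA or another kinase, remains open and untested.

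Interferon response genes were higher in the H89 library, with a list median of at least 1.13 in each of the 3 phase classes and at least 1.18 in both sets of clusters, which argued against phase shares or subpopulation shares as the whole cause. The leukocyte genes Ptprc, Laptm5 and Tyrobp together had 0.149 UMIs per 100 H89 cells, which argued against leukocytes that express these genes. They were picked from 21 markers after the counts were seen, so the outcome was known. Of the other markers, Cd68 had 1661 UMIs with H89 and 290 with DMSO, Csf1r 243 and 83, and Lyz2 90 and 10. Itgam went the other way, with 1 and 9. For Ifi27l2a, outside the list, the 25th percentile per thinned H89 cell was 7 UMIs, above the DMSO 75th percentile of 1 plus the 3.63 that free RNA could give, which argued against a minority of cells for this gene. For B2m (3 UMIs against 1 plus 3.52) and for the summed list genes (31 against 21 plus 23.2) a minority of cells cannot be told apart from a difference in most cells, because of free RNA. An effect of H89 and a difference between the cultures, such as a trigger of interferon in the H89 culture, remain open and untested.

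A hypothesis for clusters 2 and 7 is that As4.1 cells hold subpopulations that differ in chromosome copy number, with fewer copies of part of chromosome 15 in these clusters. In the test, 79.2% of the chromosome 15 genes were lower in clusters 2 and 7 in the H89 library and 79.7% in the DMSO library, which is consistent with the hypothesis. The share lower was higher still on chromosome 13, at 85.6% and 89.03%, with a smaller median difference. On chromosome 1 it was 68.9% and 68.6%, so chromosome 15 does not stand alone. Along chromosome 15, 65.2% of the first 181 genes and 93.3% of the last 180 were lower with H89. With DMSO it was 67.2% of the first 177 and 92.1% of the last 177. The parts of chromosome 13 were alike, at 84.1% and 87.1% with H89 and 88.1% and 89.9% with DMSO. The test named chromosome 15 only. Chromosome 15 had been noticed first in the same cells, and DNA was not measured, so regulation of many genes on the chromosome may also give this pattern.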
